A study of Homo sapiens with 6 samples.

How the data were processed

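Polyadenylated RNA of SKOV3 cells was sequenced in 6 libraries, 3 control and 3 treated with 150 µg/ml bevacizumab for 24 h, and groups and replicate numbers were taken from the sample titles. The deposited values are FPKM per gene, in a table of 36345 gene names by 6 libraries, per the file headers. The submitters' processing notes name fastp 0.20.0, HISAT2 2.1.0, featureCounts 1.6.5 and edgeR, without roles or order, and the genome build GRCh38. The annotation release, the strand setting and any filter on reads are not given in the sources used here. FPKM divides reads by gene length and library total, so a few very abundant transcripts, or a library whose reads favour some GC contents or lengths, shift the values of all other genes.

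The values were whole multiples of the value of 1 read, so reads were recovered. For all 36345 gene names a gene length was found at which the 6 values came out as whole reads (100% of them within 0.001 of a whole number). Lengths up to 400000 bases were tried, so for a gene above 0 in only 1 library this is a weak check. It held for all 31512 genes above 0 in 2 or more libraries. Among 14065 tested genes with a unique exon length in GENCODE 29, the recovered length equalled it for 1525. Recovered reads summed to between 99.64% and 99.66% of the library totals. Totals ran from 25461411 to 29495173 reads, so 3 reads, the floor taken for a gene at 0 reads, equal 0.102 to 0.118 FPKM in a transcript of 1 kb. Floors cover counting error only. A gene whose reads share a divisor with its length can be off by a whole factor. Recovered reads were therefore used only for depth, for low genes, to compare pairs of libraries, to build the simulated libraries and in 1 alternative. Recovered counts of libraries within a group differed by 8.22 to 105.16 chi-square units per degree of freedom, so no pair within a group looked like a repeat deposit. Pairs across groups were not compared this way.

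For the main test, log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with group as the only term, moderated variances with a trend on level, two-sided, over genes with a mean FPKM of at least 1 over the 6 libraries. The pseudocount of 1 understates the log2 change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a second count asked for at least a 2-fold change. The design leaves exact permutation tests with a smallest possible share of 0.1, so the p-values rest on limma's pooling of variances over genes. Each of 31 gene lists, fixed with the tests, groups and alternatives before the data were examined, was tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over lists. Camera with an estimated correlation and fry were run beside it. Of the 574 list and marker genes, 40 names were not in the table under that symbol, and 15 of these were matched by another symbol; the rest were not used here.

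The text names genes by a rule set in advance. It takes every tested VEGF ligand and receptor, the genes past the threshold with non-overlapping groups or, since none passed, the 10 of these with a symbol and the smallest p, and up to 4 members of each list with the smallest p. The most abundant transcripts, the parents of copied genes, list members quoted for contrast and the marker with the highest level in each set are named outside that rule. They were chosen after their values were seen. Some genes and a list that the rule covers are not reported here. Coordinates, gene types, GC content and transcript length come from GENCODE 29 on GRCh38, matched by gene name for 34790 of the 36345 names. GC content was available for 98.8% of tested genes.

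The scripts were tested on simulated data. In simulated libraries with independent genes and nothing changed, limma called 0 of 14289 genes, with 715 at an unadjusted p under 0.05. With 200 genes changed it recovered 16.4% at 1.5-fold, 64.2% at 2-fold and 89.4% at 4-fold, with 6 false calls among 14326 genes. The same test on the real libraries with 200 genes multiplied is given in the results.

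The counts of genes and of lists called by camera, and the values of named genes and lists, were recomputed under 24 alternatives, 17 planned and 7 chosen after seeing the data, besides the other list tests. The fry call was recomputed under 9 settings, and camera with an estimated correlation was run in the main setting only. The planned ones changed the pseudocount, the filter, the scaling, the variance model, library weights and the replicate block, and left out each library in turn. The added ones were limma voom on recovered reads, removal of each library's smooth trend with GC content, transcript length and level (splines with 5 degrees of freedom), the same with a replicate block, the first principal component as a covariate, protein-coding genes only, gene-by-gene library weights, and leaving out control 1 and control 3. Scaling factors came from median ratios or from trimmed means computed in R.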

Results

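The series measured polyadenylated RNA in SKOV3, a human ovarian carcinoma cell line, by RNA sequencing. Per the labels, 3 libraries came from control cells kept in a medium the labels call condition medium, and 3 came from cells given 150 µg/ml bevacizumab in that medium for 24 h. Bevacizumab is a humanised monoclonal antibody that binds the growth factor VEGFA. The comparison asks which transcripts of the tumour cells themselves differ after exposure to the antibody. Library totals, recovered from the FPKM values (reads scaled by transcript length and library total), were 26609097, 28575297 and 29086413 reads for bevacizumab 1, 2 and 3. They were 29495173, 25461411 and 26767575 reads for control 1, 2 and 3. All levels below are means ± SD in FPKM over 3 libraries per group, and all log2 changes are bevacizumab minus control on the log2(FPKM + 1) scale. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

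VEGFA, the antibody's target, was transcribed at 71.7 ± 2.45 FPKM in control cells and 82.6 ± 9.62 FPKM in bevacizumab-treated cells. Its log2 change was 0.20 with a 95% interval of -0.05 to 0.44, and it did not pass the test (limma, adjusted p = 0.997). The gene lies on chromosome 6 at 43770184 to 43786487 (GRCh38, GENCODE 29). Bevacizumab 1 had 71.5 FPKM of VEGFA, within the range of the control libraries, while bevacizumab 2 and 3 had 88.0 and 88.4 FPKM. VEGFB stood at 65.4 ± 15.7 and 64.4 ± 7.64 FPKM in control and treated cells, and the lymphangiogenic ligand VEGFC at 18.4 ± 1.18 and 19.4 ± 2.34 FPKM. VEGFD and PGF stayed below a mean of 1 FPKM and were not tested.

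Among the receptors, the co-receptors NRP1 and NRP2 were the abundant ones. NRP1 was at 61.5 ± 12.5 FPKM in control and 67.0 ± 4.31 FPKM in treated cells, and NRP2 at 92.0 ± 7.98 and 101 ± 5.27 FPKM. KDR, which encodes VEGF receptor 2, was at 1.91 ± 0.429 and 1.93 ± 0.11 FPKM. FLT4, which encodes VEGF receptor 3, was at 0.425 ± 0.138 and 0.509 ± 0.0981 FPKM, and FLT1, which encodes VEGF receptor 1, had between 0 and 2 reads in each library. Of the 10 ligands and receptors of this list 6 were tested, 0 rose and 0 fell, and 5 of the 6 estimates were positive. The list as a whole did not pass camera (mean log2 change 0.09, adjusted p = 0.197), a test of a list against all other genes. It passed without bevacizumab 1 (mean 0.15, adjusted p = 0.0326), while without bevacizumab 3 the mean was 0.05 (adjusted p = 0.624).

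**Figure D1:**
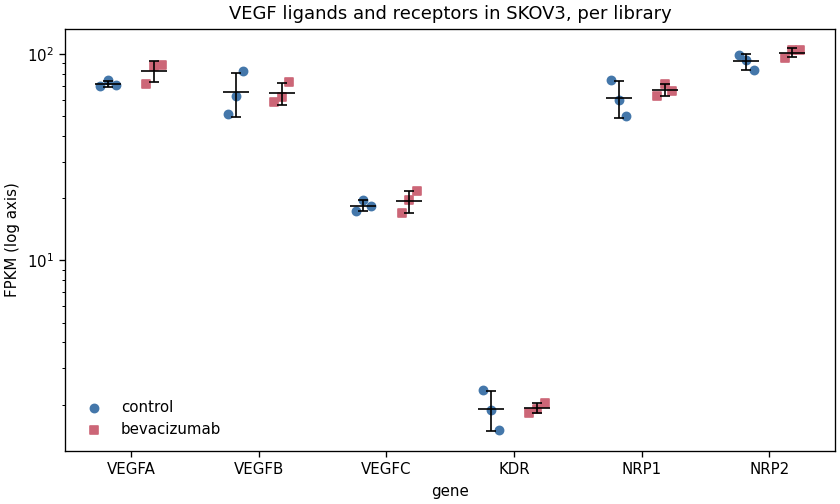
Expression of the 6 tested VEGF ligands and receptors in each library, in FPKM on a log axis; circles are the 3 control and squares the 3 bevacizumab libraries, and bars give the mean ± SD. The groups overlap for all 6 genes, VEGFA at 71.7 ± 2.45 against 82.6 ± 9.62 FPKM included.

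Across the transcriptome, 0 genes rose and 0 fell after bevacizumab among 14289 tested, of which 11787 were protein-coding, and 0 changed at least 2-fold (limma with Benjamini-Hochberg adjustment, smallest adjusted p = 0.997). At an unadjusted p under 0.05 there were 170 genes, 100 higher and 70 lower in treated cells, where chance alone gives about 714. Limma voom on the recovered reads also called 0 genes, with 151 at an unadjusted p under 0.05. The 3 libraries of one group lay entirely above or below those of the other for 828 genes (5.8%), against 10% by chance. The most abundant transcripts were those of the ferritin heavy chain FTH1 (6833 ± 1436 FPKM in control, 7066 ± 377 in treated cells), of the mitochondrial MT-CO1 (5405 ± 122 and 4963 ± 159.5), and of ACTG1, ENO1 and ACTB.

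The precision set how large a change could be seen. On the scale of FPKM + 1, the 95% interval of the log2 change lay within a 2-fold change for 13593 genes (95.1%). It lay within a 1.5-fold change for 11021 (77.1%). For low genes these bounds allow a larger fold in FPKM itself. RNA5SP410, for example, had a log2 change of 1.08 on that scale and a ratio of mean FPKM of 4.09. When 200 randomly drawn genes were multiplied in the treated libraries, the test recovered 94% of them at a 4-fold change, 45.5% at a 2-fold change and 0% at a 1.5-fold change. Changes of 2-fold or less were therefore more often missed than found here gene by gene. These shares hold for 200 genes changed at once.

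None of the genes with the smallest p-values passed the threshold (adjusted p = 0.997 for RNA5SP410). RNA5SP410, a 5S ribosomal RNA pseudogene on chromosome 16 at 35745989 to 35746094, had the smallest unadjusted p of all (0.000251). It went from 0.572 ± 0.177 to 2.34 ± 0.489 FPKM, a log2 change of 1.08, on a mean of 4.33 reads per library. RNU6-1099P, SNORA3B and NDUFB1P1 likewise rested on means of 4.5, 5.5 and 7 reads, and MIR4767 on 23, while CBSL, MT-TY and TSSK5P had means of 102, 179 and 183 reads. The long non-coding RNA MIR5689HG was at 1.96 ± 0.572 and 3.62 ± 0.307 FPKM. The mitochondrial tyrosine tRNA gene MT-TY was at 110.0 ± 6.14 and 86.4 ± 7.24 FPKM.

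CBSL, a near-identical copy of the cystathionine beta-synthase gene CBS, had 3.37 ± 1.51 FPKM in control and 1.0 ± 0.276 FPKM in treated cells, whereas CBS itself had 1.37 ± 0.160 and 1.42 ± 0.326 FPKM. The values of CBSL and NDUFB1P1 are uncertain, because reads can be split between such copies in counting. TSSK5P, a pseudogene on chromosome 8, was at 6.24 ± 0.159 and 8.31 ± 0.384 FPKM.

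**Figure D2:**
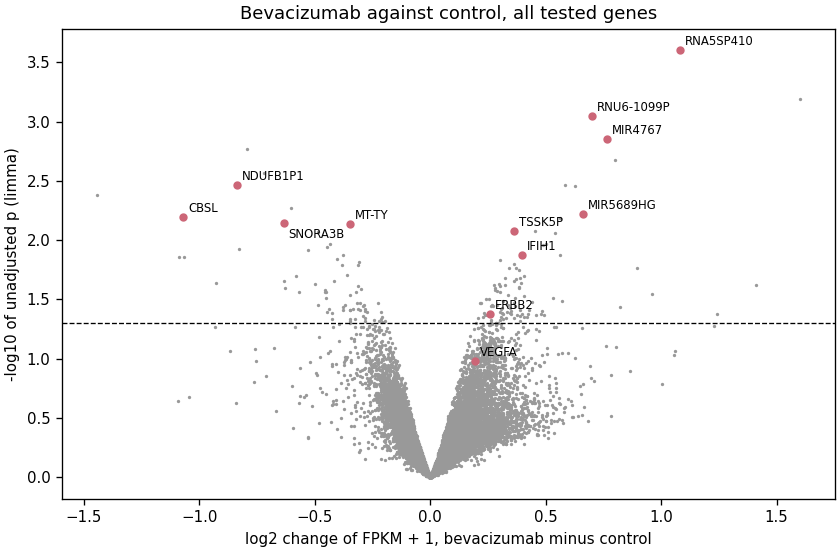
Each point is 1 of the 14289 tested genes, with the log2 change of FPKM + 1 (bevacizumab minus control) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The dashed line marks an unadjusted p of 0.05, above which 170 genes lie; named points are genes given in the text, and 0 genes passed after adjustment.

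Receptor tyrosine kinases and ovarian carcinoma markers included the most abundant of the genes with an unadjusted p under 0.05. ERBB2, the receptor kinase gene expressed at a high level in SKOV3, was at 878 ± 21.9 FPKM in control and 1054 ± 122 FPKM in treated cells, with all 3 treated libraries above all 3 controls. Its log2 change was 0.26 (95% interval 0.01 to 0.50, unadjusted p = 0.0421, adjusted p = 0.997). PAX8, a transcription factor of the Müllerian lineage, was at 94.1 ± 1.34 and 105 ± 6.75 FPKM, and mesothelin (MSLN) at 1.27 ± 0.319 and 1.71 ± 0.217 FPKM. EGFR, with 106 ± 30.1 and 123 ± 3.08 FPKM, ranged in the controls from 75.2 to 136 FPKM.

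Of the 8 ovarian carcinoma markers tested 0 rose or fell singly, and 6 estimates were positive. As a list they lay higher than other genes by camera (mean log2 change 0.15, adjusted p = 0.0327), the only list with an upward call, though with adjusted p = 0.47 with an estimated correlation. The call ended without control 1 (adjusted p = 0.653, mean 0.127), without control 2 (0.0684, mean 0.149) and without bevacizumab 3 (0.214, mean 0.108), against a mean of 0.146 with all libraries. The marker call also ended with median-ratio scaling (camera, adjusted p = 0.0872, mean 0.107) and trimmed-mean factors (0.1, mean 0.106). It ended too with quantile normalization (0.0722, mean 0.117) and without a filter on low values (0.108, mean 0.127). The markers passed under 12 of the 24 alternatives. The 17 receptor tyrosine kinases and ligands did not pass as a list (adjusted p = 0.342).

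Camera called lists of mitochondrial and ribosomal protein genes as lower in treated cells with its preset correlation, and with an estimated correlation called none of them (adjusted p = 0.47). Of the 24 nuclear-encoded genes of the mitochondrial respiratory chain 23 had a negative estimate, with a mean log2 change of -0.12. SDHB, a subunit of complex II, was at 139.6 ± 14.1 FPKM in control and 118 ± 11.9 FPKM in treated cells, and COX7C of complex IV at 342 ± 41.4 and 299 ± 18.4 FPKM. Of the 28 ribosomal protein genes all 28 had a negative estimate, with a mean of -0.15. RPL7 was at 908 ± 17.0 and 787 ± 64.0 FPKM and RPSA at 757 ± 154 and 621 ± 81.7 FPKM. Of the 13 mitochondrially encoded genes 10 had a negative estimate, with a mean of -0.08, and MT-CO2 was at 4465 ± 234 and 3847 ± 213 FPKM.

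By camera these 3 lists lay lower than other genes, with adjusted p = 2.84e-08 for the respiratory chain, 1.22e-10 for ribosomal proteins and 0.000126 for the mitochondrially encoded genes. For each of the 3 the adjusted p = 0.47 with an estimated correlation, which came to 0.53, 0.87 and 0.40 for these lists. Without control 3 the respiratory chain and ribosomal protein calls ended (adjusted p = 0.0592 and 0.295), at means of -0.05 and -0.03, while without control 1 the means were -0.18 and -0.26. The mean over the ribosomal protein genes was 0.30 above the mean of the 6 libraries in control 3 and -0.15 in control 1, with bevacizumab 1, 2 and 3 at 0.04, -0.14 and -0.11.

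The other 4 downward calls by camera had smaller mean changes. The 24 DNA replication and S phase genes had 19 negative estimates and a mean log2 change of -0.06 (adjusted p = 0.000319), with the helicase factor CDC45 at 70.2 ± 2.19 and 61.6 ± 3.32 FPKM and the sliding clamp PCNA at 154 ± 4.19 and 139.6 ± 9.06 FPKM. The 18 oxidative stress and NRF2 genes had 13 negative estimates and a mean of -0.08 (adjusted p = 0.00715), with thioredoxin TXN at 552 ± 28.6 and 489.8 ± 69.7 FPKM. The 19 glycolysis genes had 14 negative estimates and a mean of -0.05 (adjusted p = 0.0282), with ENO1 at 4738 ± 761 and 4223 ± 185 FPKM. The 19 ribosome biogenesis genes had 11 negative estimates and a mean of -0.03 (adjusted p = 0.0282), with NOP56 at 209 ± 9.41 and 187 ± 9.78 FPKM. With an estimated correlation the adjusted p was 0.47 for DNA replication, oxidative stress and ribosome biogenesis, and adjusted p = 0.628 with an estimated correlation for glycolysis.

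The DNA replication and mitochondrially encoded calls stayed past the threshold when any 1 library was left out, though the mitochondrially encoded mean was -0.04 without bevacizumab 3 (adjusted p = 0.0479). Both ended with quantile normalization (adjusted p = 0.0562 and 0.843) and after removal of the GC, length and level trends (0.058 and 0.989), where the mitochondrially encoded mean was 0.01 and 0.02. The DNA replication mean was -0.058 and -0.042 there, against -0.055 in the main test. The glycolysis call ended without bevacizumab 2 (adjusted p = 0.24), bevacizumab 3 (0.0596, at a mean of -0.049 against -0.047), control 2 (0.197) or control 3 (0.928), and the oxidative stress call without bevacizumab 3 (0.0596, mean -0.054) or control 3 (0.481, mean -0.023). The glycolysis mean turned to 0.007 without control 3. The ribosome biogenesis call ended without bevacizumab 2 (0.0586, mean -0.029), bevacizumab 3 (0.214, mean 0.001), control 1 (0.419, mean 0.02) or control 2 (0.0684, mean -0.023), against a mean of -0.026 with all libraries.

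In all, 30 lists fixed before the data were examined had at least 5 tested members, and camera with its preset correlation of 0.01 called 8 of them, 7 down and 1 up. With an estimated correlation it called 0, with 0 lists at an unadjusted p under 0.05 and a smallest unadjusted p of 0.0619. Of the 496 genes tested in all 31 fixed lists, 0 passed over all genes and 0 passed when adjusted over the list alone. In 5 lists the median, the mean and the direction of the test differed in sign, among them mitosis and G2/M, with a median log2 change of -0.03, a mean of 0.07 and a downward test.

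Fry, which tests whether a list's genes move on balance in one direction and compares them with no other genes, called 1 list. This was the interferon-stimulated genes, where 15 of 20 estimates were positive, the median log2 change was 0.12 and the adjusted p was 0.0236. IFIH1, an intracellular sensor of double-stranded RNA, was at 1.18 ± 0.0997 and 1.88 ± 0.252 FPKM, with a log2 change of 0.40 (unadjusted p = 0.0133). IFIT3 was at 3.35 ± 0.549 and 4.24 ± 0.325 FPKM and OAS3 at 32.7 ± 1.61 and 36.8 ± 1.76 FPKM, while MX1 was at 3.20 ± 0.171 and 3.0 ± 0.459 FPKM. The fry call ended when any 1 library was left out, with adjusted p from 0.0661 without bevacizumab 3 to 0.22 without bevacizumab 2, at list means of 0.08 to 0.09 against 0.09 with all libraries. It also ended with median-ratio scaling (0.836, mean 0.04), quantile normalization (0.93, mean 0.03) and removal of the trends (0.526, mean 0.06). Camera did not call the list (adjusted p = 0.118) except without control 3 (0.0428).

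**Figure D3:**
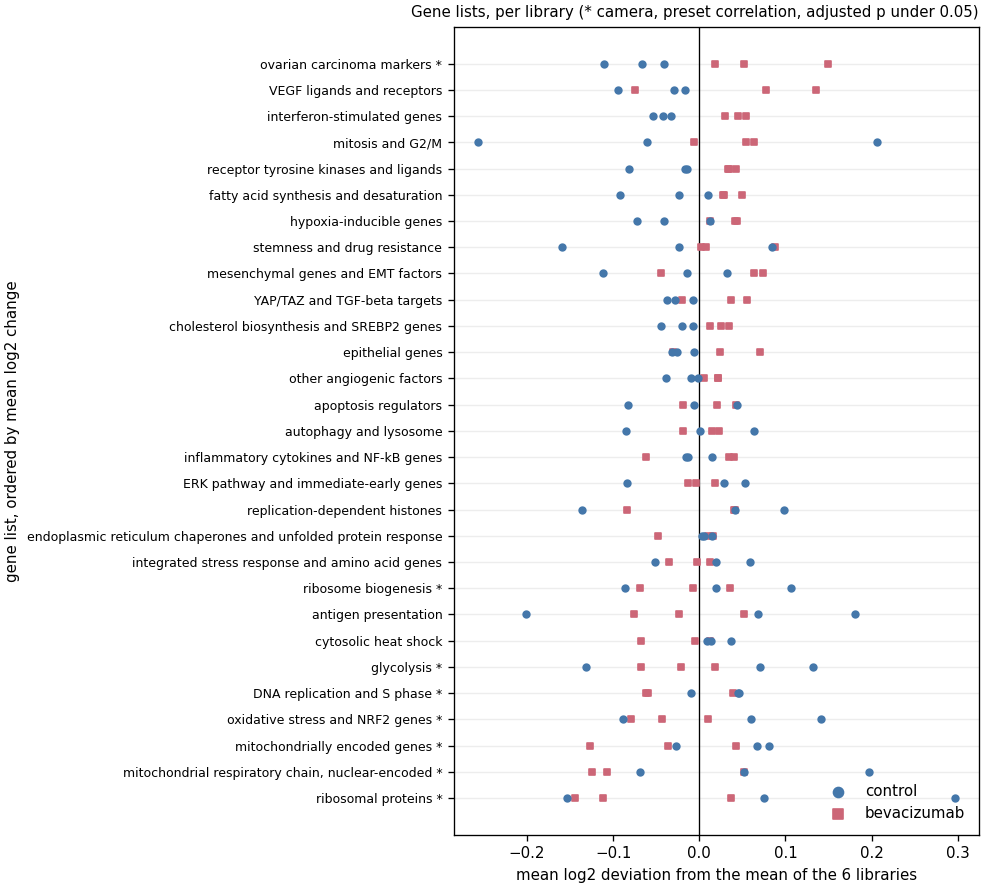
Mean log2 deviation of the gene lists named in the text in each library from the mean of the 6 libraries; circles are control and squares bevacizumab libraries, and lists are ordered by their mean log2 change. Asterisks mark the 8 lists called by camera with its preset correlation. For ribosomal proteins the controls spread from -0.15 to 0.30. For interferon-stimulated genes all 3 treated libraries lie above all 3 controls. The same holds for other lists, among them ovarian carcinoma markers, receptor tyrosine kinases, other angiogenic factors and the lipid gene lists.

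Genes of oxygen sensing and vessel growth did not pass as lists. The 21 hypoxia-inducible genes had 17 positive estimates and a mean log2 change of 0.07 (camera, adjusted p = 0.228), with the prolyl hydroxylase EGLN1 at 14.1 ± 0.759 and 16.7 ± 1.99 FPKM and the carbonic anhydrase CA12 at 17.8 ± 0.478 and 19.2 ± 0.615 FPKM. The 15 other angiogenic factors had a mean of 0.03 (adjusted p = 0.911), with PDGFB at 2.25 ± 0.293 and 2.76 ± 0.470 FPKM and ANGPTL4 at 6.83 ± 1.77 and 5.65 ± 0.731 FPKM.

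Cell division genes went both ways. Of the 22 tested mitosis and G2/M genes 10 estimates were positive and 12 negative (camera, adjusted p = 0.355). Their mean log2 change of 0.07 became 0.20 without control 1 and turned to -0.04 without control 3. The proliferation marker MKI67 was at 93.3 ± 46.1 and 117 ± 6.27 FPKM and TOP2A at 312 ± 176 and 375 ± 31.2 FPKM, while cyclin B1 (CCNB1) was at 282 ± 21.5 and 262 ± 19.2 FPKM. The 17 apoptosis regulators (adjusted p = 0.94) and the 6 replication-dependent histones (0.663) were not called either. Among them BMF was at 14.4 ± 1.67 and 17.0 ± 2.68 FPKM.

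The other stress response lists were not called by camera in the main test. The adjusted p was 0.118 for the 20 integrated stress response and amino acid genes, 0.118 for the 18 endoplasmic reticulum chaperones and unfolded protein response genes, and 0.052 for the 14 cytosolic heat shock genes. The heat shock list, with a mean log2 change of -0.04, passed without bevacizumab 1 (0.0326) or bevacizumab 2 (0.0385), and with voom on recovered reads (0.041). Its mean was -0.016 without bevacizumab 3 (0.214) and -0.013 after removal of the trends (0.986). The integrated stress list passed without control 1 (0.0236, mean -0.047) and at a mean FPKM of at least 5 (0.0448). Without control 3 the integrated stress mean turned to 0.008 (0.928), against -0.017 with all libraries. The co-chaperonin HSPE1 was at 139.9 ± 8.57 and 114 ± 21.4 FPKM, the disulphide isomerase PDIA3 at 287 ± 12.99 and 257 ± 15.7 FPKM, and DDIT3 at 23.1 ± 0.601 and 21.3 ± 1.55 FPKM. Of the metallothioneins only MT1X and MT2A were tested, too few for a list test, with MT2A at 1087 ± 165 and 1072 ± 72.0 FPKM.

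The lipid gene lists were not called. Positive estimates were 16 of 21 for cholesterol biosynthesis (camera, adjusted p = 0.628) and 13 of 14 for fatty acid synthesis and desaturation (adjusted p = 0.228), where the median log2 change of all genes was itself 0.037. With median-ratio scaling the list means went from 0.047 to 0.004 and from 0.07 to 0.028. FASN, the fatty acid synthase, was at 360.3 ± 33.3 and 399.9 ± 31.7 FPKM, and ACACA at 81.0 ± 11.7 and 90.7 ± 2.24 FPKM.

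Signalling and cell state lists were not called by camera in the main test. The adjusted p was 0.628 for the 13 inflammatory and NF-kB genes, 0.228 for the 11 antigen presentation genes, 0.407 for the 19 ERK pathway genes and 0.911 for the 19 YAP/TAZ and TGF-beta targets. It was 0.911 for the 17 mesenchymal genes, 0.94 for the 13 epithelial genes, 0.599 for the 8 stemness and drug resistance genes and 0.505 for the 19 autophagy and lysosome genes. Antigen presentation passed without control 1 (mean log2 change -0.14, adjusted p = 0.00392), while without control 3 its mean was 0.05 (0.432). The cytokine IL6 was at 5.89 ± 0.352 and 4.83 ± 0.207 FPKM, the membrane protease MMP14 at 2.03 ± 0.0899 and 2.79 ± 0.456 FPKM, vimentin (VIM) at 951 ± 52.9 and 817 ± 74.2 FPKM, and keratin 18 (KRT18) at 154 ± 27.4 and 128 ± 14.1 FPKM. POU5F1 was at 5.95 ± 0.744 and 7.38 ± 0.672 FPKM.

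Markers of other cell types were mostly low. Of the endothelial, macrophage and erythroid markers 0 reached a mean of 1 FPKM, and the highest endothelial marker was ERG at 0.53 FPKM in control and 0.74 FPKM in treated cells. The fibroblast marker COL1A1 was at 34.4 and 42.6 FPKM, the lymphocyte marker IL7R at 5.64 and 5.58 FPKM, and the mesothelial marker UPK3B at 4.39 and 5.12 FPKM. A mean of 1 FPKM was reached by 4 of the 9 fibroblast and 5 of the 8 mesothelial markers with values. Of 10 lymphocyte markers only 4 had values, and 1 of these reached it.

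The controls differed among themselves more than the treated libraries did. The median within-group SD over genes was 0.20 on the log2 scale in controls and 0.10 in treated libraries. The first principal component held 70.5% of the variance, with control 1 at -30.8 and control 3 at 39.0, and the treated libraries between them. Transcripts in the lowest quintile of GC content (up to 41%) had a median log2 deviation of 0.34 in control 1 and -0.40 in control 3, and those in the highest quintile (57.9% or more) -0.20 and 0.16. Without control 1 the number of genes at an unadjusted p under 0.05 was 3338 instead of 170, with 0 genes called and a smallest adjusted p of 0.138.

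**Figure D4:**
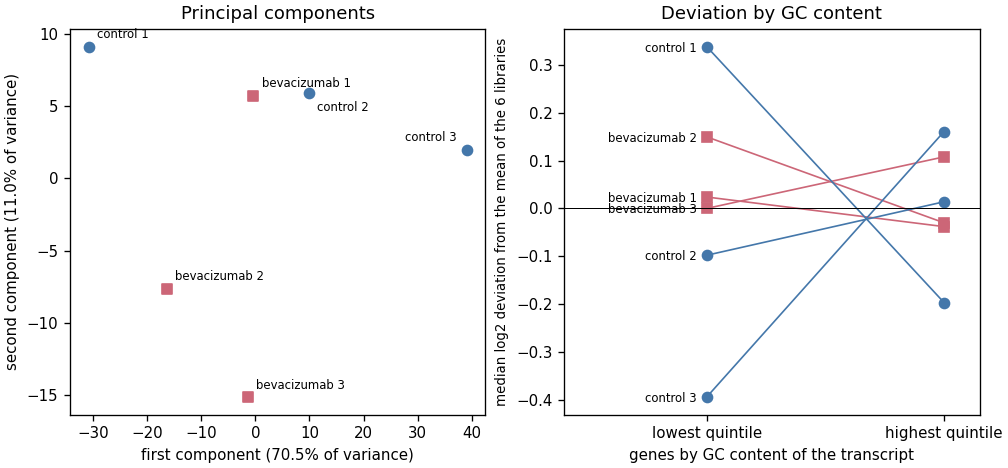
Left, the 6 libraries on the first and second principal components (70.5% and 11% of variance) of log2(FPKM + 1). Right, each library's median log2 deviation from the mean of the 6 libraries for transcripts in the lowest and the highest quintile of GC content; control 1 and control 3 lie at opposite ends, at 0.34 and -0.40 in the lowest quintile.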

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

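The number of genes called was 0 under 21 of the 24 alternatives, 0 to 0 when each library was left out. Planned library weights gave 4258 genes, 35 of them at least 2-fold, but their fit did not converge and put a weight of 6649 on control 2. Gene-by-gene weights, added after seeing the data, gave 561 and 26, with 12.37 on control 2 and at most 1.66 on any other library, so both rest on 1 control. Leaving out control 1 and control 3, also chosen after seeing the data, gave 2 genes, 2 of them at least 2-fold. The lone control is assumed to vary like the treated libraries there, and both genes are low: AC244015.1 had 0.34, 0 and 1.13 FPKM in the 3 controls, and FP700111.3 had 8.73 FPKM in control 2 and 0 in all others. Genes at an unadjusted p under 0.05 ranged from 71 to 6336.

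The 8 list calls became 4 without a filter on low values, 5 with trimmed-mean factors, 2 with quantile normalization, 2 after removal of the GC, length and level trends (also with a replicate block), 0 with an estimated correlation and 1 by fry. They ranged from 4 to 10 when each library was left out. The mean of the mitochondrially encoded genes reversed to 0.016 once the trends were removed, with or without the replicate block, and was 0.01 with quantile normalization. Library weights also called antigen presentation (adjusted p = 0.019, or 0.0184 gene by gene), the planned weights also called the ERK pathway (0.0448), and heat shock passed with a pseudocount of 0.1 (0.049), a mean FPKM of at least 5 (0.041) and protein-coding genes only (0.0378). The cause was not tested beyond these values.

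The replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.26, -0.21 and 0.33 over genes, and bevacizumab 2 correlated best with control 1 (0.58). The paired fit with a replicate block called 0 genes and 8 lists, with 115 genes at an unadjusted p under 0.05. Of 3130 values of named genes under the alternatives 2923 were classed as the same as in the main test, 107 as stronger and 100 as moved. This class does not mean an equal estimate, and no named gene was called in the main test. With median-ratio scaling, for example, the median log2 change of all genes went from 0.037 to -0.002. The sign of the estimate differed for 44 values, and 117 of 132 genes never changed sign. Depth limits the low genes, where a few reads set the value.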

Other observations

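The tests of the GC content, length and level trends on the first principal component and on the list calls, the test with an estimated correlation as an explanation and the counts of splits for genes were chosen only after the result was seen. The others below were set before it.

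Some genes not named above describe the cells. MUC16, which encodes the serum marker CA125, was at 0.12 ± 0.126 FPKM in control and 0.171 ± 0.0188 FPKM in treated cells, while KRT7 was at 821 ± 168 and 759 ± 46.2 FPKM. The oestrogen receptor gene ESR1 was at 5.33 ± 0.700 and 6.56 ± 0.173 FPKM, with all 3 treated libraries above all 3 controls (adjusted p = 0.997). SERF1B, which has a near-identical copy, had 34.0 FPKM in control 1 and 2.89 to 4.21 FPKM in the other 5 libraries. These genes were chosen after their values were seen.

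Several cell division transcripts spread widely over the controls, with the treated libraries between. TOP2A was at 503, 276 and 157 FPKM in control 1, 2 and 3 and at 351 to 410.5 FPKM in the treated libraries, and CENPF at 85.3, 30.2 and 16.1 FPKM. CDC20 and UBE2C went the other way, CDC20 at 397, 480 and 541 FPKM and UBE2C at 189, 207 and 238 FPKM. Over the 22 members, which are not independent replicates, the log2 difference of control 1 from control 3 had a Spearman correlation of 0.75 with transcript length and -0.85 with GC content. The mean of the list ranged by 0.463 (log2) over the controls and still by 0.324 (standard error over members 0.104) after the GC, length and level trends were removed.

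Against 50 other genes matched to each member on GC content, length and level, the mitosis list kept a mean excess of 0.322 (standard error 0.102), with 17 of 22 members above their matched genes. The median excess was 0.088, and 7 members lay above by more than 0.5 (TOP2A, MKI67, ANLN, CENPF, CENPE, KIF11 and CDK1), without which the mean excess was 0.038. Both tests argue against a dependence on these 3 properties shared with other genes as the whole of the spread. The matched genes still moved the same way by 0.141. Those 7 members carry the excess and were picked by it, so its fall without them was fixed. Matching was loose for some of them, such as MKI67 (length 12678 against a matched mean of 10906) and TOP2A (GC content 39.1% against 40.3%), which can add to their excess. It was close for ANLN (length 4787 against 4691), with an excess of 1.01, and KIF11 (4860 against 4838), with 0.56. The members are not independent, so the standard errors may be too small. A difference in the growth state of the control cells may, as a hypothesis, add to the spread, but 5 of the 22 members lay below their matched genes. The design names no difference among controls, so no biological explanation was tested.

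The first principal component separated control 1 from control 3. Depth did not account for it: with every library thinned to the smallest total it still held 70% of the variance. A few abundant genes did not either, since median-ratio scaling left 69.3%. Trends with GC content, length and level explained at least 51.1% of the variance of the deviations in control 1 and control 3, consistent with a part in the pattern, yet 54% of the variance stayed on the first component after their removal, with the same libraries at its ends. RNA quality or library preparation may differ between these controls, but no label names a batch, and no biological explanation was tested.

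For the 8 list calls, members that move together between libraries whatever the group remain an open explanation. With an estimated correlation 0 lists passed, but this does not single that explanation out. The heat shock list had an estimated correlation of -0.002, below the preset 0.01, and a camera p of 0.0156 with the preset. With an estimated correlation no camera p was under 0.0619, so p rose there without members moving together. Removing the trends left the respiratory chain call (adjusted p = 0.00297, mean log2 change -0.119 before and -0.106 after, SD over members 0.06 and 0.09). Its distance from the median of all genes went from -0.156 to -0.103, still just above that SD. By the set criterion this went against the trends as its whole cause. After the removal, however, the list stood at -0.10, 0.04 and 0.22 in control 1, 2 and 3. It stood at 0.03, -0.11 and -0.07 in bevacizumab 1, 2 and 3. The groups overlapped and what remained leaned on control 3, so the trends stay open for this list. Ribosomal proteins also passed (adjusted p = 0.0206), but their mean went from -0.146 to -0.061 with an SD of 0.07, so what remained was within the spread of the members and the trends stay open for it. Both p-values use the preset correlation. The calls of the 5 other downward lists ended and their distance from the median of all genes shrank. It went from -0.084 to -0.018 for glycolysis, -0.118 to 0.019 for mitochondrially encoded genes and -0.092 to -0.039 for DNA replication. For oxidative stress it went from -0.112 to -0.048 and for ribosome biogenesis from -0.063 to -0.031. The SDs over members of these lists were 0.09, 0.09, 0.09, 0.12 and 0.14 before and 0.07, 0.08, 0.06, 0.12 and 0.13 after. The trends may account for these calls, but the removal cannot decide it. Trends were fitted to the treated libraries too, so a change shared by abundant genes would be removed with them. Part of the shrinkage also came from the median of all genes, which went from 0.037 to -0.003. The list mean itself went from -0.055 to -0.042 for DNA replication and from -0.026 to -0.034 for ribosome biogenesis. The call of the ovarian carcinoma markers ended too (adjusted p = 0.058), yet their distance went from 0.109 to 0.117 (SD 0.12 and 0.13), so its loss says nothing for the trends. An effect of bevacizumab stays open and untested beyond the comparison itself.

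The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 0 genes, 0 genes changed at least 2-fold and 8 lists, and the highest of the other 9 splits gave 0, 0 and 7. Only the real split, 1 of 10, had as many lists. As many genes were called in 10 of 10 splits, which a real count of 0 fixes in advance, so it decides nothing. A split with bevacizumab 1, bevacizumab 2 and control 1 on one side had 3230 genes at an unadjusted p under 0.05, against 170 for the real one, and one with bevacizumab 1, control 2 and control 3 had 3151. Counts several times the real one point to a structure of the libraries. Both splits part control 1 from control 3, but 4 other splits that do so had 83, 119, 472 and 473 such genes, so parting them does not by itself give a high count.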
